A study of Mus musculus with 2 samples.

How the data were processed

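RNA of spermatogonial progenitor cells from testes of mice at 8 days after birth was extracted with Tri-Reagent, selected for poly(A), fragmented and copied with random primers, and paired-end reads were obtained on a HiScanSQ instrument, per the labels' protocols. The protocol describes no step that marks the strand, so reads of overlapping genes on opposite strands may not be separable. There was 1 wild-type and 1 Dnmt3l knockout library, each grouped by the genotype in its labels. CASAVA 1.9, TopHat2 2.0.8 and Cufflinks 2.1.1 and the build mm10 are named, without their settings, per the submitters' processing notes. Each deposited file is a transcript annotation with an FPKM, its lower and upper bounds and a coverage per transcript. It lists 30073 RefSeq transcripts, those at 0 included, and transcript models assembled from the reads of that library, 20579 in the wild-type and 20415 in the knockout library. The FPKM values were used as the authors deposited them. The score column of the deposited files was not used. The coverage was used only in an alternative and for relative depth.

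RefSeq identifiers were given gene symbols by accession for 29628 of 30079 identifiers, by the gene names in the files for 101, 34 and 17 more (current, older and withdrawn names), and by exon overlap with the GENCODE M21 annotation of the same build for 296; 3 stayed without a name. Assembled models of 300 nt or more joined the gene with which they shared most exon bases on the same strand, and models without a strand joined only with a share of 0.5 or more of their bases. Shorter models were left out, since the 608 of the knockout library alone summed to 1073459 FPKM, against 402672 FPKM for its RefSeq transcripts, and for 94.1% of them the FPKM lay outside its own bounds. The value of a gene was the sum over its transcripts and models, and its bounds were the sums of their bounds. The bounds cover the estimate within a library, not the spread between animals, and no depth or interval from counts can be given because counts are not in the files. In all, 23236 genes were named, and 13797 with 1 FPKM or more in at least 1 library and a longest spliced transcript of 300 nt or more were compared as log2((knockout FPKM + 1)/(wild-type FPKM + 1)), with a pseudocount of 1.

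No test between the genotypes was made, since there was 1 library of each. Counts of genes at least 2-fold higher or lower and the correlation across genes were computed. For 34 gene lists fixed before the data were examined, the median log2 ratio of measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, where at least 5 members were measured, as a description of these libraries. A match on 10 expression by 10 length bins was added after seeing the data. Named genes were fixed by rule: Dnmt3l; the 12 highest and 12 lowest ratios among genes of 5 FPKM or more in the higher library whose bounds did not overlap, predicted and unnamed genes left out; up to 4 members of each list with the largest absolute ratio, and other members where their list is described; and the 5 most abundant genes of each library. Because all 24 genes of the second part were listed at 0 in 1 library, a further 12 in each direction were taken, after seeing the data, among genes above 0 in both libraries, at 1 locus, and at least 2-fold different in the same direction at the exon level. The exon level is the mean over the RefSeq exon bases of a gene of the summed FPKM of all models covering each base, on either strand, and end levels are the same over the 1000 nt at each end of the longest RefSeq transcript. Both are sums of the FPKM of whole models, not read coverage.

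Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter or a filter of 10 FPKM, centring on the median gene, upper-quartile scaling, scaling to the total without the 50 most abundant genes, the most abundant RefSeq transcript of a gene (assembled models have no counterpart in the other library), the coverage attribute, no length limit, counts restricted to genes with bounds apart or at 1.5-fold and 4-fold, and the mean of list members. Alternatives added after seeing the data were genes above 0 in both libraries, RefSeq transcripts only, the exon level, and the removal of the median of 20 length bins. The computation was tested on simulated data for the comparison of the knockout with the wild-type library over 13797 genes: all 200 genes changed 4-fold were recovered, 0 unchanged genes were called, 5% of 100 unchanged lists lay outside the central 95% of random lists, and an added length trend with a Spearman rho of -0.868 became -0.012 after adjustment. The simulated noise was small and independent between libraries, only genes with a mean of 5 FPKM or more were changed, and none was at 0 in 1 library. The simulation therefore checks the computation, and does not show how many 2-fold differences between the real libraries are false. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.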

Results

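Poly(A) RNA of spermatogonial progenitor cells (SPCs), the germ cells from which spermatogenesis is maintained, was sequenced from testes of C57BL/6 mice at 8 days after birth. There were 2 libraries, 1 from wild-type mice and 1 from mice lacking Dnmt3l, a catalytically inactive partner of the de novo DNA methyltransferases. The series title names the role of DNMT3L in quiescence of these cells, so the comparison of the libraries asks which transcripts differ when it is missing, those of the cell cycle among them. With 1 library per genotype no difference has a replicate check, and every value below describes these libraries. Values are FPKM per gene, a measure of fragments scaled by transcript length and library size. Read counts are not given in the files, so the depth of each library is unknown. The coverage that corresponded to 1 FPKM had a median of 3.13 in the wild-type and 3.45 in the knockout library, a ratio of 1.10, which is the relative depth if fragment lengths were alike. Of 13797 genes compared, all reached 1 FPKM in at least 1 library.

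Dnmt3l (chromosome 10, 78042287 to 78063615, plus strand, mm10) was listed at 1.67 FPKM in the wild-type library, with summed bounds of 0.79 to 2.68, and at 0 in the knockout library, with an upper bound of 0. In the wild-type library the RefSeq transcript NM_019448, with 13 exons, carried 0.921 FPKM (bounds 0.497 to 1.37), and an assembled model of 11 exons within it carried 0.75 FPKM. Both RefSeq transcripts of the gene were at 0 in the knockout library. The wild-type level was low, above that of 11.9% of the genes compared. Of 1976 genes with 1 to 3 FPKM in the wild-type library, 64 (3.24%) were listed at 0 in the knockout library, and 3 of these, Dnmt3l, Smim6 and 1700008K24Rik, also had an upper bound of 0. An upper bound of 0 also occurred for Cnot1, a gene that every cell uses, which was at 82.4 FPKM in the wild-type library. The neighbouring gene Icosl was at 8.09 FPKM in the wild-type and 10.6 FPKM in the knockout library. The label of the knockout library was therefore met by the listed value, while a listed 0 alone does not separate absence from a failed estimate.

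Across the transcriptome, markers of macrophages, Sertoli, Leydig and endothelial cells and immediate early genes were higher in the knockout library, and the medians of differentiating spermatogonia markers, mitotic genes and piRNA pathway genes lay below the median gene when assembled models were summed. At least 2-fold higher values, on the scale of log2(FPKM + 1), were listed for 1063 genes and at least 2-fold lower values for 485. Of these, 337 of the higher genes were listed at 0 in the wild-type library and 184 of the lower genes at 0 in the knockout library. Of the 726 higher and 301 lower genes above 0 in both libraries, 361 and 172 were also at least 2-fold different at the exon level. The median gene, among genes of 1 FPKM or more in both libraries, had a log2 ratio of 0.20, and relative to it 677 genes were higher and 750 lower. Thus 68.7% of the 2-fold differences were higher in the knockout library as deposited, and 47.4% were after centring, 49.7% with upper-quartile scaling, 42.8% scaled to the total, 42.6% with the coverage attribute and 50.8% with RefSeq transcripts alone. Ratios called relative below have this median subtracted, and all are on the log2(FPKM + 1) scale, which understates the differences of low genes. Across genes, which are not independent replicates, the libraries correlated with a Pearson r of 0.903 and a Spearman rho of 0.914 over log2(FPKM + 1).

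The log2 ratio fell with transcript length (Spearman rho = -0.40 across genes). Its median was 0.54 over 1213 genes whose longest transcript was under 1000 nt and -0.51 over 93 genes of 12000 nt or more. Each gene list with a median is therefore given with its percentile among random lists matched on expression, and a further percentile with lists matched on expression and length, chosen after seeing the data.

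**Figure D1:**
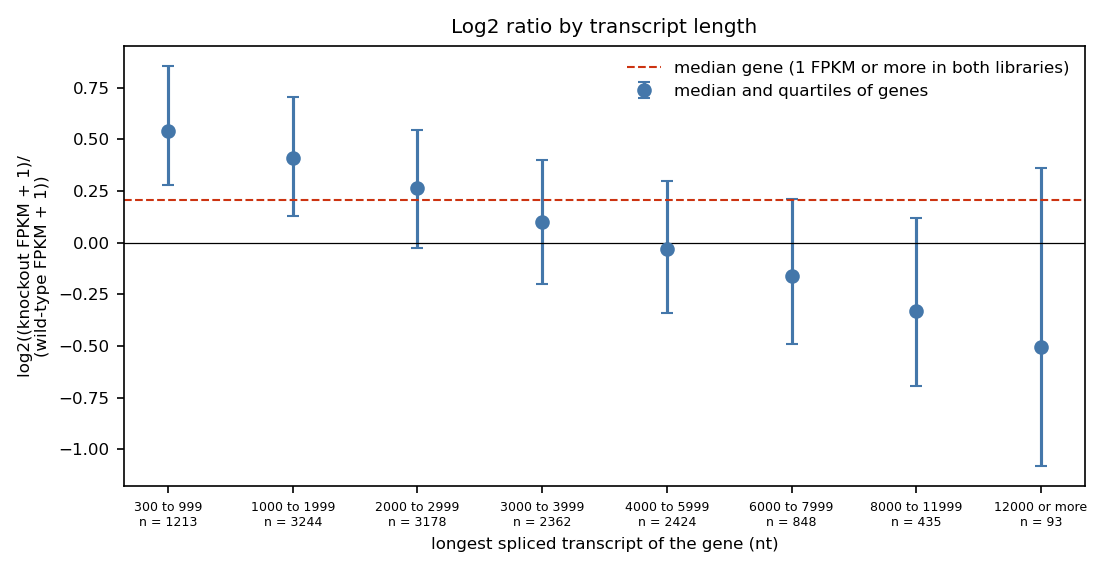
Log2 ratio of the knockout over the wild-type library (vertical axis) by length of the longest spliced transcript in nt (horizontal axis); points are medians over the genes of each length class, bars run from the lower to the upper quartile, and the dashed line marks the median gene at 0.20. The medians go from 0.54 in the shortest class to -0.51 in the longest.

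Sertoli cell markers had a relative median log2 ratio of 0.54 (percentile 100 among the random lists, and 100 with length matched), and 24 of 27 lay above the median gene. Rhox5, a homeobox gene of the X chromosome that Sertoli cells express (chromosome X, 37754608 to 37808878), was at 4.18 FPKM in the wild-type library (bounds 2.92 to 5.55) and 36.8 FPKM in the knockout library (30.3 to 43.2). Amh, the anti-Müllerian hormone, was at 21.2 and 87.4 FPKM. Defb19 was at 71.4 and 184.8 FPKM, and Clu at 179.5 and 420.2 FPKM. Tsx was listed at 0 in the wild-type library and at 5.93 FPKM in the knockout library. Kitl, the ligand of KIT, was lower at 10.01 and 5.21 FPKM.

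Macrophage and leukocyte markers had the highest relative median of the lists, 0.81 (percentile 100 on both matchings). At least 2-fold higher were 9 of 18 as deposited and 5 of 18 relative to the median gene. The complement genes C1qa (60.3 and 142.7 FPKM in the wild-type and knockout libraries) and C1qb (66.8 and 161.9 FPKM), and the invariant chain gene Cd74 (6.79 and 18.8 FPKM) were among the 9, and the lysozyme gene Lyz2 was at 141.3 and 261.1 FPKM, a log2 ratio of 0.88. Cd68 was at 24.6 FPKM in the wild-type library and listed at 0 in the knockout library, as were its neighbours Mpdu1 and Senp3. Ptprc (2.29 and 1.98 FPKM) and Mrc1 (34.8 and 29.5 FPKM) were also lower, while 15 of the 18 lay above the median gene. Leydig cell markers had a relative median of 0.45 (percentile 99.6, and 98.0 with length matched). Insl3 was at 22.1 and 58.5 FPKM, Cyp17a1, a steroidogenic enzyme, at 8.76 and 20.8 FPKM, and Hsd3b1 at 16.0 and 32.6 FPKM, while Srd5a1 was listed at 0 in the wild-type library and at 7.53 FPKM in the knockout library. Endothelial markers had a relative median of 0.41 (percentile 99.6, and 99.5 with length matched), with Pecam1 at 3.37 and 11.05 FPKM, Ramp2 at 17.3 and 41.2, Ecscr at 2.35 and 6.31, and Plvap at 9.64 and 21.0. Peritubular and stromal markers did not follow them: their median was 0.20 as deposited and -0.005 relative to the median gene (percentile 22.5, and 37.8 with length matched), although Tagln (28.6 and 51.8 FPKM, with a log2 ratio of -0.39 for RefSeq transcripts alone), Myl9 (108.9 and 178.5), Tpm2 (27.1 and 44.1) and Des (10.3 and 17.0) were higher. The log2 ratio of Tagln at the exon level was 0.466. Of the erythroid genes 3 were measured, too few for a median: Hbb-bs was at 2.22 and 7.82 FPKM, Hba-a1 at 6.53 and 13.99, and Hbb-b2 at 1.94 and 3.15.

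**Figure D2:**
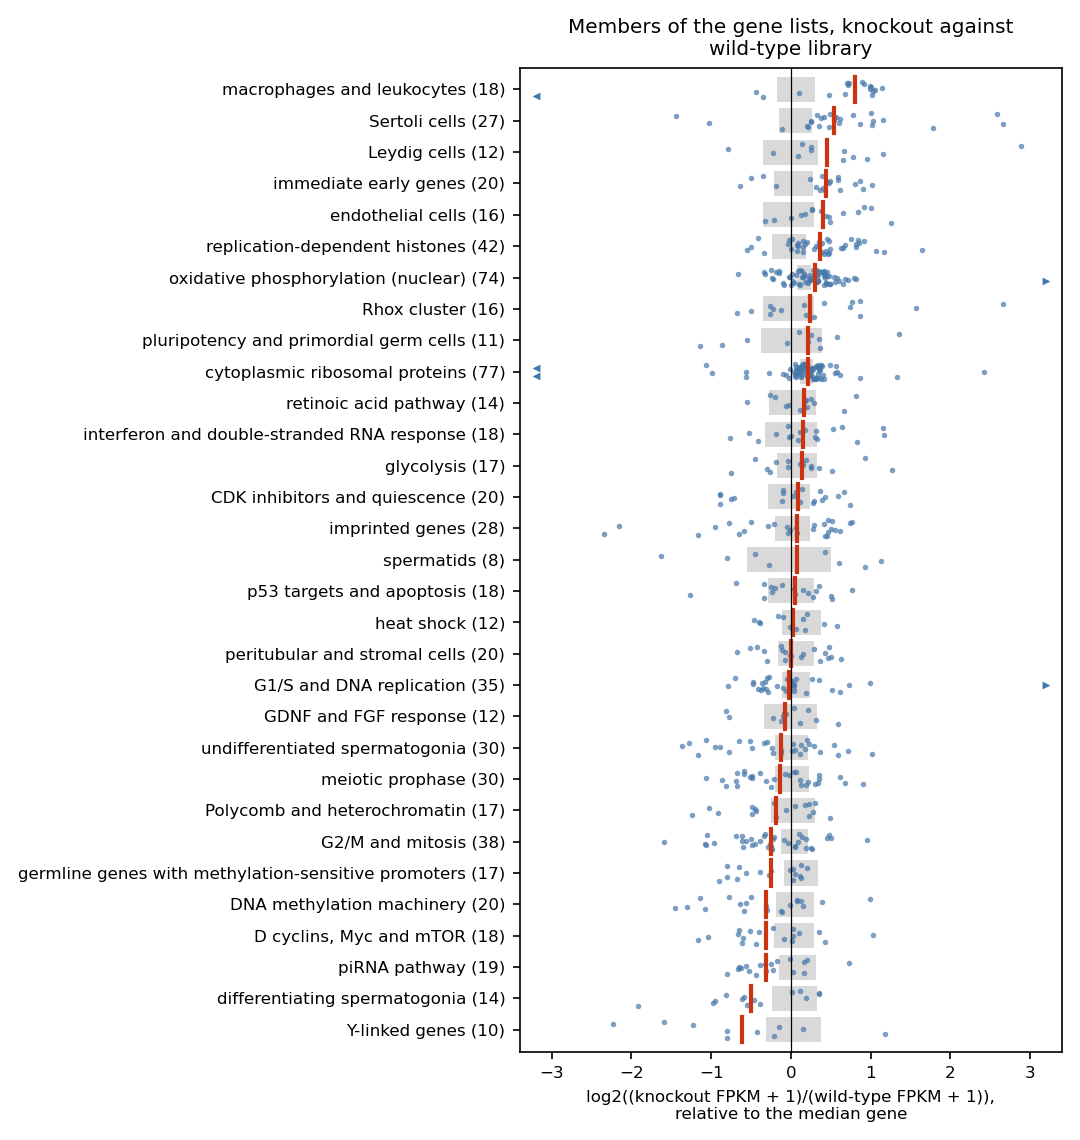
Log2 ratio of the knockout over the wild-type library relative to the median gene (horizontal axis) for the measured members (points, with their number in parentheses) of each gene list with a median, the X-linked one left out (vertical axis); red lines mark list medians, grey bars the central 95% of 10000 random lists matched on expression, and triangles members beyond the axis. Macrophage markers have a median of 0.81 and differentiating spermatogonia markers one of -0.51.

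Among the germ cell lists, markers of differentiating spermatogonia had a relative median of -0.51 (percentile 0.02, and 0 with length matched), with 9 of 14 below the median gene and 5 above it. As deposited the median was -0.30, with a bootstrap interval over genes of -0.58 to 0.31, and Kit alone was at least 2-fold lower. Kit, the receptor tyrosine kinase whose appearance marks differentiation of spermatogonia (chromosome 5, 75574987 to 75656721), was at 21.7 FPKM (19.8 to 23.5) in the wild-type library and 5.93 FPKM (5.38 to 6.51) in the knockout library, a relative log2 ratio of -1.92. The higher members were Esx1 (7.01 and 10.8 FPKM), Tex15 (48.9 and 72.2, with a log2 ratio of -0.98 at the exon level), Rhox13 (8.79 and 11.8), Rarg (16.6 and 20.9) and Nanos3 (24.3 and 28.4). Among the lower ones, Sohlh2 was at 33.9 and 19.5 FPKM, Dmrtb1 at 8.75 and 4.78, and Elavl2 at 13.0 and 8.19. These germ cell differences stood beside the higher somatic markers, whose macrophage list had a relative median of 0.81. Markers of undifferentiated spermatogonia went both ways, with a median of 0.08 as deposited and -0.13 relative to the median gene (percentile 8.52, and 7.13 with length matched). Id4, an inhibitor of differentiation gene, was higher at 14.4 and 35.0 FPKM, and so were Gfra1, the GDNF co-receptor gene, at 27.4 and 48.5 FPKM, and Nanos2 at 4.60 and 9.58 FPKM. Zbtb16, which encodes the progenitor transcription factor PLZF, was lower at 55.4 and 27.9 FPKM, as were Itga6 at 24.9 and 10.6 and Neurog3 at 9.63 and 4.06. At the 5′ end of Zbtb16 the level was 50.6 in the wild-type and 8.44 in the knockout library, and at its 3′ end 55.4 and 27.9. At the 5′ end of Gfra1 the levels were 27.3 and 13.9, and its log2 ratio with RefSeq transcripts alone was -0.01, so its direction depended on the part of the transcript. Its log2 ratio at the exon level was 0.342.

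Meiotic prophase genes had a median of 0.06 as deposited and -0.14 relative (percentile 7.48, and 1.11 with length matched). Syce3, of the synaptonemal complex, was at 30.4 and 66.5 FPKM, and Rec8, a meiotic cohesin, at 12.04 and 23.1, while Mei4 was at 4.06 and 1.79. Mlh3, at 6.10 and 11.5 FPKM, had a log2 ratio of -0.22 at the exon level, where the levels of all models are averaged over its exon bases. Of the spermatid genes 8 were measured, with a relative median of 0.07 (percentile 63.4, and 30.9 with length matched). Tnp1 was at 3.27 and 8.36 FPKM, Odf1 at 0.0667 and 1.69, Spaca1 at 3.18 and 6.30, and Gapdhs was at 1.68 FPKM and listed at 0 in the knockout library.

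Mitotic genes were lower relative to the median gene, with a G2/M median of -0.25 (percentile 0.1, and 0.07 with length matched) and -0.04 as deposited. With RefSeq transcripts alone the G2/M median was 0.09 as deposited, below the median of 0.162 over all genes in that setting. Mki67, the proliferation antigen Ki-67, was at 38.3 and 20.6 FPKM and Kif20a, a kinesin of cytokinesis, at 58.3 and 31.4. With RefSeq transcripts alone their log2 ratios were 0.06 and 1.01, so the lower values appear only when assembled models are counted. At the exon level, which counts all models, the ratios were -0.792 and -0.358. Cenpf was at 42.6 and 15.7 FPKM, and its log2 ratio was 0.81 with RefSeq transcripts alone and -1.188 at the exon level. The phosphatase gene Cdc25b was higher at 9.29 and 22.0 FPKM. The G1/S and DNA replication list did not stand apart: its median was 0.18 as deposited and -0.03 relative (percentile 15.5, and 25.7 with length matched). Within it Cdk2, the cyclin-dependent kinase of the G1/S transition, was at 39.8 and 70.8 FPKM and Gins1 at 15.9 and 31.4. Tyms was at 11.5 and 27.6 FPKM but had a log2 ratio of -0.13 with RefSeq transcripts alone and 0.329 at the exon level. Gins2 was listed at 0 in the wild-type library and at 19.3 FPKM in the knockout library. CDK inhibitors and quiescence genes had a relative median of 0.09 (percentile 77.3, and 64.6 with length matched). Of these, Cdkn1a, which encodes p21, was at 3.95 and 8.58 FPKM, Trp53 at 36.3 and 67.2 and Btg2 at 19.98 and 35.3, whereas Foxo1 was at 37.3 and 22.9. With RefSeq transcripts alone the log2 ratio of Btg2 was -1.32 and the median of the list -0.08, while at the exon level they were 0.545 and 0.212. D cyclins, Myc and mTOR genes had a relative median of -0.31 (percentile 0.46, and 2.71, inside the central 95%, with length matched). At the exon level the length-matched percentile was 2.18, just outside it. The median was -0.105 as deposited and 0.10 with a filter of 10 FPKM, where the median over all genes was 0.264. Cdk6 was at 5.84 and 2.503 FPKM, Mycl at 7.76 and 3.92 and Ccnd3 at 34.7 and 54.6. Mtor was at 33.6 and 80.2 FPKM when assembled models were summed, while its log2 ratio was -0.46 at the exon level.

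Genes of the DNA methylation machinery had a relative median of -0.31 (percentile 0.3, and 4.52, inside the central 95%, with length matched). At the exon level the length-matched percentile was 0.14, outside it. The median was -0.104 as deposited and 0.078 with a filter of 10 FPKM, where the median over all genes was 0.264. Dnmt3a was at 20.9 and 22.1 FPKM and Dnmt3b at 31.1 and 23.5. Tet3, a 5-methylcytosine dioxygenase, was at 14.6 and 5.60 FPKM, with a log2 ratio of 0.64 for RefSeq transcripts alone and -1.137 at the exon level. Tdg was at 6.56 and 2.52 FPKM and Dppa3 at 1.74 and 0.438. Ehmt2 was at 119.6 and 275.8 FPKM, with a log2 ratio of -0.23 for RefSeq transcripts alone and 0.124 at the exon level. The piRNA pathway had a relative median of -0.31 (percentile 0.1, and 0.15 with length matched), with Piwil2 at 93.7 and 61.6 FPKM, Tdrd9 at 30.5 and 21.8, Tdrkh at 57.6 and 41.9, and Gtsf1 higher at 80.4 and 154.0. Germline genes with methylation-sensitive promoters, of which 10 of 17 belong to another list as well, had a relative median of -0.25 (percentile 0.07, and 0.02 with length matched), with Dazl at 222.6 and 136.7 FPKM and Taf7l at 219.5 and 145.1. As deposited, the medians of the piRNA and promoter lists were -0.11 and -0.05, and with RefSeq transcripts alone they were 0.14 and 0.13, with log2 ratios of 0.39 for Piwil2 and 0.13 for Taf7l. At the exon level the medians were -0.085 and -0.079, and the log2 ratios of Piwil2 and Taf7l were -0.573 and -0.471. The median over all genes was 0.162 with RefSeq transcripts alone.

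Imprinted genes had a relative median of 0.07 (percentile 66.3, and 75.5 with length matched). The paternally expressed gene Peg3 (chromosome 7, 6705960 to 6730419, minus strand) was at 21.6 FPKM (19.99 to 23.3) in the wild-type and 4.13 FPKM (3.76 to 4.51) in the knockout library, and its neighbour Zim1 at 12.4 and 2.46 FPKM. In the knockout library alone, a model assigned to the plus strand over the 3′ end of the Peg3 models stood at 33.96 FPKM. It lies almost wholly outside the RefSeq exons and was not counted for Peg3. The protocol describes no step that marks the strand, so the reads of that model may not be separable from those of Peg3. The direction of the Peg3 difference at the 3′ end is therefore uncertain. At the 5′ end of Peg3, which that model does not reach, the level was 19.4 in the wild-type and 0.611 in the knockout library. Igf2r was at 23.3 and 11.5 FPKM. H19, at 103.1 and 159.6 FPKM, and Dlk1, at 228.0 and 385.0 FPKM, were higher, and Rasgrf1 was at 1.06 and 3.04. Genes of the Rhox cluster had a relative median of 0.24 (percentile 94.8, and 35.0 with length matched). Of these, Rhox8 was at 22.8 and 49.1 FPKM, Rhox10 at 13.0 and 28.3, and Rhox2f was listed at 0 in the wild-type library and at 2.42 FPKM in the knockout library. Over 584 X-linked genes the median was 0.19 as deposited and -0.01 relative (percentile 27.4, and 1.34 with length matched). The largest ratios there belonged to genes listed at 0 in 1 library, Cmc4 (12.7 FPKM in the knockout library) and Ribc1 (10.2) in the wild-type library and Armcx5 (12.5 FPKM in the wild-type library) in the knockout library. The 10 Y-linked genes had a relative median of -0.61 (percentile 0.07, and 0.27 with length matched), with Zfy1 at 5.80 and 0.666 FPKM, Zfy2 at 2.65 and 0.391, and Uty at 4.57 and 1.75. Gm47283 was higher, at 130.5 and 343.2 FPKM, as was Uba1y at 93.8 and 120.0, and Eif2s3y was at 34.9 and 34.8. The median of -0.41 as deposited became 0.01 with no FPKM filter, where the median over all genes was 0.121.

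Immediate early genes were higher, with a relative median of 0.44 (percentile 99.95, and 99.9 with length matched), beside higher macrophage, Sertoli and endothelial markers (0.81, 0.54 and 0.41), cell types that can express such genes too. Ier2 was at 29.4 and 69.5 FPKM, Junb at 26.7 and 58.9, Zfp36 at 34.4 and 73.5 and Ier3 at 9.05 and 19.3. Nuclear genes of oxidative phosphorylation had a relative median of 0.30 (percentile 99.85, and 80.2 with length matched) and replication-dependent histones one of 0.37 (percentile 99.97, and 72.8 with length matched), so neither stood apart among genes of like length. Only 22 of the 42 histone genes measured reached 1 FPKM in the wild-type library, and the others passed the filter through the knockout library. Ndufa12 was at 50.03 and 103.0 FPKM and H2ac15 at 0.321 and 2.43. Cytoplasmic ribosomal proteins had a relative median of 0.21 (percentile 56.5, and 1.05 with length matched).

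The remaining lists lay inside the central 95% of the random lists on both matchings, whose percentiles are given in that order. They were pluripotency and primordial germ cell genes (relative median 0.22, percentiles 86.7 and 72.6; Dppa4 at 19.3 and 59.1 FPKM), the GDNF and FGF response (-0.08, percentiles 30.2 and 50.9; Spred1 at 20.4 and 13.1) and the retinoic acid pathway (0.17, percentiles 84.1 and 72.0; Dhrs3 at 10.1 and 21.4 and Rara at 14.9 and 28.1, the latter with a log2 ratio of -0.05 for RefSeq transcripts alone). They also took in Polycomb and heterochromatin genes (-0.18, percentiles 6.52 and 27.0; Suz12 at 29.7 and 14.04 and Cbx5 at 20.5 and 11.2) and heat shock genes (0.03, percentiles 16.1 and 40.6; Hspb1 at 25.1 and 43.9). At the exon level the length-matched percentile of the Polycomb list was 0.74, outside the central 95%, and the log2 ratio of Rara was 0.701. The interferon and double-stranded RNA response (0.15, percentiles 82.8 and 79.4), p53 targets and apoptosis (0.05, percentiles 58.0 and 68.9) and glycolysis (0.14, percentiles 65.0 and 81.5) completed them. Bst2 was at 35.0 and 91.5 FPKM, Mx2 at 0.55 and 3.01, Phlda3 at 9.06 and 18.7, and Trp53inp1 at 19.01 and 8.57. The mitochondrially encoded genes had no named transcript. Of 32 lists with a median, 14 lay outside the central 95% of random lists, and 13 did with length matched. For lists of unrelated genes 1.6 would. Members of a cell type or pathway list can vary together and some lists share members. The 1.6 is therefore not the number to be awaited between 2 libraries of 1 genotype.

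The 24 genes picked by the rule of size, 12 in each direction, were all listed at 0 in 1 library, and no fold is given for them. Listed at 0 in the wild-type library were Elob (499.8 FPKM in the knockout library), Cox20 (102.2), Pam16 (91.5), Fkbp2 (74.1), Zfas1 (71.2), Thyn1 (62.9), Zswim7 (58.7), Acat3 (55.8), Spcs1 (55.8), Bcl2l12 (51.2), Dxo (50.9) and Dnajc19 (43.2). Listed at 0 in the knockout library were Rpl26 (147.2 FPKM in the wild-type library), Cnot1 (82.4), Senp3 (82.1), Ube2e1 (49.8), Tomm40 (42.0), Rpp38 (37.1), Mpdu1 (36.2), Tubgcp4 (35.0), Cenpv (34.5), Deaf1 (31.7), Cd68 (24.6) and Lias (24.0). Many of these genes, such as the ribosomal protein gene Rpl26 and the mitochondrial import gene Tomm40, are used by every cell. For most of the 24 the exon level, counting all models, was also 0 in that library. In the wild-type library these were Pam16, Fkbp2, Zswim7, Spcs1, Bcl2l12 and Dxo. In the knockout library they were Cnot1, Senp3, Ube2e1, Tomm40, Rpp38, Mpdu1, Cenpv, Deaf1, Cd68 and Lias. A listed 0 did not always mean uncovered exons: the exon level was 1362 in the wild-type and 1733 in the knockout library for Rpl26, 40.6 and 53.6 for Cox20, and 38.6 and 79.2 for Acat3.

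A further choice, made after seeing the data, took genes above 0 in both libraries, at 1 locus and also at least 2-fold different at the exon level. They had 5 FPKM or more in the higher library and bounds apart. Predicted or unnamed genes were passed over, 4 higher and 2 lower. Among the named genes, the highest ratios in the knockout library belonged to Zfp575 (0.91 and 28.7 FPKM), Cd2 (0.448 and 14.5), Cd209c (5.59 and 69.4), Cpne8 (10.4 and 117.8), Csta2 (0.712 and 15.3) and Sfi1 (6.27 and 65.6). Tmc2 (0.183 and 9.16), Kcnh6 (0.323 and 9.95), Nme8 (0.162 and 8.34), the zinc transporter gene Slc39a4 (0.784 and 12.5), Rhox5 and Prss45 (0.411 and 8.27) followed. The level at the 3′ end of Cpne8 was 1.93 in the wild-type and 0 in the knockout library, so its difference lay in other parts of the gene. The lowest ratios belonged to Efcab8 (19.6 and 2.29 FPKM), Pdpr (19.6 and 2.54), Thoc2l (7.51 and 0.725), Speer4cos (7.46 and 0.804), Peg3, Lnpep (11.03 and 1.77), Zfy1, Usp34 (77.8 and 18.8), Kmt2c (24.1 and 5.36), Mdn1 (150.9 and 37.6), Zim1 and Mib1 (15.6 and 3.62). The longest transcripts of the lower genes had a median of 4487 nt and those of the higher genes one of 2156 nt. At the 3′ end of Usp34 the level was 44.3 in the wild-type and 61.1 in the knockout library, the opposite direction.

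The most abundant genes were nearly the same in both libraries. Eef1a1, which encodes translation elongation factor 1 alpha, led with 3252 FPKM in the wild-type and 3459 FPKM in the knockout library. Rps24 (2594 and 3272 FPKM) and Rps28 (2252 and 3342) were among the top 5 of both, and Rplp2 (1865 and 2766 FPKM) among those of the knockout library. Rps15a was also among the top 5 of the wild-type library, at 2535 FPKM, and at 124.8 FPKM in the knockout library, but its log2 ratio was -0.36 at the exon level and 2.79 with RefSeq transcripts alone.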

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

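The tests of a general somatic share, of cell preparation and of merged loci were chosen only after the results were seen. These signals lie outside the genes compared. A model over the mitochondrial genome, which belongs to no named gene, was listed at 2464.7 FPKM in the knockout library, where the wild-type library had models at 185.8 and 1948.9 FPKM. An unspliced model of 2164 nt on the plus strand (chromosome 7, 6703894 to 6706057), listed at 33.96 FPKM in the knockout library alone, covers the 3′ end of the longer Peg3 models assembled in the wild-type library, and the minus-strand Peg3 model of the knockout library was at 4.13 FPKM. Assembled loci in no gene at 10 FPKM or more numbered 93 in the knockout library alone and 83 in the wild-type library alone.

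Markers of macrophages, Sertoli, Leydig and endothelial cells were higher in the knockout library. The macrophage median was 0.64 (bootstrap interval over genes 0.42 to 0.68) after the length trend was removed, above the bound of 0.3, which argues against length as its cause. Length-adjusted medians were 0.447 (0.29 to 0.556) for Sertoli and 0.486 (0.17 to 0.649) for endothelial markers. The Leydig one was 0.352 (-0.132 to 0.739), an interval that includes 0. The macrophage median exceeded the length-adjusted peritubular and stromal median by 0.43 (0.22 to 0.68), so in these libraries the latter list did not rise as the former did. These were the highest and lowest of the somatic medians, paired after they were seen. The interval is over genes and does not measure the spread between preparations. The test therefore cannot decide on a larger share of all somatic cells alike. All 18 macrophage markers were at 1 FPKM or more in the wild-type library and none is in another list. More macrophages may have been in the preparation of the knockout library, and the labels name no sort that would remove them. Of the 18 markers, 15 lay above the median gene, but Ptprc (relative log2 ratio -0.346), Mrc1 (-0.434) and Cd68 lay below it. With the length trend removed, Ptprc was at -0.045 and Mrc1 at -0.133. The 0 listed for Cd68 in the knockout library was shared with its neighbours Mpdu1 and Senp3, so it may be a failed estimate. With 1 library per genotype, a difference in macrophage number was not established, and genotype and cell preparation cannot be told apart.

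The log2 ratio fell with transcript length. With RefSeq transcripts alone rho was -0.39, which argues against the summing of assembled models as the cause. Over the 91 genes of the germ cell lists rho was -0.30 (-0.50 to -0.09), so the trend was present among them too. These lists join germ cell stages whose relative medians differed, -0.13 for undifferentiated and -0.51 for differentiating spermatogonia. A shift among stages could therefore act within them, and the test cannot decide on a shift in cell makeup. In 3752 genes of 4000 nt or more the log2 ratio of 3′ to 5′ end level was higher in the knockout library by a median of 0.119 (0.0858 to 0.152), as lower coverage of 5′ ends there would give, so RNA integrity or library preparation may contribute. Over the 9121 genes with end levels, rho with length was -0.309 for the gene ratio, -0.275 at the 3′ end and -0.459 at the 5′ end. The trend thus remained at 3′ ends, so lower 5′ end levels did not account for most of it on this measure. End levels are sums over assembled and RefSeq models, not read coverage, and are blind to a loss within a model. How much of the trend read coverage of 5′ ends accounts for is therefore undecided, and a dependence on genotype stays open.

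Genes listed at 0 in 1 library and at 5 FPKM or more in the other numbered 163 for the wild-type and 79 for the knockout library. Of 241 such genes at 1 locus, 73.9% (exact 95% interval 67.8 to 79.3) had another gene within 1 kb, against 38.3% of other genes of 5 FPKM or more. The interval treats the genes as independent. Neighbours such as Cd68, Mpdu1 and Senp3 were listed at 0 together, so it may be too narrow. Merging of adjoining genes into 1 assembled locus is a candidate explanation for some of these zeros, and no biological explanation was tested for them. Exons taken into a neighbour's model would have an exon level above 0. Among the genes picked by the rule of size this held for Elob, Cox20, Zfas1, Thyn1, Acat3, Dnajc19, Rpl26 and Tubgcp4. For the others, Cd68, Mpdu1 and Senp3 among them, the exon level was 0 in the library that listed 0. Absorption into a neighbour's model therefore does not explain those zeros. Whether a merged locus was left without an estimate was not tested.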

How the results depend on the processing

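The alternatives that keep genes above 0 in both libraries, RefSeq transcripts only, the exon level or the removal of the length trend were chosen after seeing the data. No paired analysis was possible because there was 1 library per genotype, and no library could be left out for the same reason; depth is unknown, so how far it limits low genes was not tested. The 4 alternatives tried for Dnmt3l could not turn its difference, since all its transcripts are listed at 0 in the knockout library. Against 1063 higher and 485 lower genes, the counts were 416 and 161 with a pseudocount of 5, 572 and 201 with a filter of 10 FPKM, 677 and 750 centred, 616 and 822 scaled to the total, 604 and 815 with the coverage attribute, 3133 and 1246 at 1.5-fold, and 268 and 134 at 4-fold. The higher count was 695 with upper-quartile scaling and 661 with the length trend removed; the lower count was 1436 for the most abundant transcript, 1392 for RefSeq transcripts only and 301 for genes above 0 in both libraries. The correlation of 0.903 became 0.947 with no filter, 0.827 with a filter of 10 FPKM, 0.81 and 0.937 with pseudocounts of 0.1 and 5, 0.814 for the most abundant transcript, 0.824 for RefSeq transcripts only and 0.949 above 0 in both. List medians scaled to the total and with the coverage attribute were -0.202 and -0.2 for undifferentiated spermatogonia, 0.446 and 0.449 for Sertoli cells, 0.733 and 0.721 for macrophages, -0.113 and -0.125 for G1/S and -0.336 and -0.343 for G2/M. Centred and upper-quartile scaled values were -0.026 and -0.032 for G1/S and -0.246 and -0.256 for G2/M, and Sertoli cells had 0.529 upper-quartile scaled. With the length trend removed Sertoli cells had 0.447, macrophages 0.641, G1/S -0.118 and oxidative phosphorylation -0.017, and the mean of macrophage markers was 0.581. A turned sign below is one of values without centring, not a crossing of the median gene. The median over all genes was 0.162 with RefSeq transcripts only, 0.165 for the most abundant transcript, 0.264 with the 10 FPKM filter and 0.121 with no filter. List medians below that turned from under 0 to above 0 stayed under these values. The sign turned for G2/M with RefSeq transcripts only (0.092), for the piRNA and methylation-sensitive promoter lists with RefSeq transcripts only and the most abundant transcript (0.143 and 0.128 in both), for CDK inhibitors and quiescence (-0.083 in both), Polycomb (-0.455 in both), the GDNF and FGF response (-0.128 and -0.17) and meiotic prophase (-0.029 and -0.116), for p53 targets with RefSeq transcripts only (-0.044), for D cyclins, Myc and mTOR (0.1) and DNA methylation (0.078) with the 10 FPKM filter, for Y-linked genes (0.011) and spermatids (-0.121) with no filter, for meiotic prophase (-0.044) and Polycomb (-0.244) at the exon level, and for Polycomb with the mean of members (-0.014). With the most abundant transcript and RefSeq transcripts only, the sign also turned for Cenpf (0.814), Mtor (-1.031), Pfkl (-0.399), Rpl21 (-0.368), Rps15a (2.788), Slc2a3 (-0.988), Tet3 (0.643), Tyms (-0.127) and Ehmt2 (-0.474 and -0.228), and for Mtor (-0.455) and Mlh3 (-0.219) at the exon level. The same held, from ratios under 2-fold, for Btg2 (-1.322), Kif20a (1.008), Mki67 (0.059), Piwil2 (0.385), Taf7l (0.128), Gfra1 (-0.014), Tagln (-0.394), Ezh1 (-0.455), Etv4 (-0.314), Hsp90ab1 (-0.145), Aldh1a2 (-0.067) and Rara (-0.167 and -0.046), so that 21 of the named genes tried turned under each of these settings. At the exon level the sign turned for 2 named genes, Mtor and Mlh3. The median of 7 lists turned when centred or upper-quartile scaled, of 9 scaled to the total, of 10 with the coverage attribute and of 13 with the length trend removed, which take away the shift of the median gene or the length trend. Beyond construction, the cause was not tested. Counting each list under each alternative, 377 medians differed from the reported one by no more than 0.5 of the width of its bootstrap interval, 91 differed by more and 9 of those called in the report turned sign.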

Other observations

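Within lists whose medians did not stand apart, single members differed. Bst2, which encodes tetherin, was at 35.0 FPKM in the wild-type and 91.5 FPKM in the knockout library, and Ifi27l2a at 10.5 and 19.7. The glucose transporter gene Slc2a3 was at 5.97 and 14.3 FPKM, though its log2 ratio was -0.988 with RefSeq transcripts alone and 1.06 at the exon level.

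The assembled loci outside named genes numbered 12054. Of these, 2494 were present in both libraries, 5216 in the wild-type library alone and 4344 in the knockout library alone.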
